A study of Homo sapiens with 16 samples.

How the data were processed

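Gene expression was measured on 16 Illumina BeadChip arrays of MDA-MB-231 cells, an established human breast cancer line of mesenchymal character. Per the labels, cells received entinostat at 2.5 µM, all-trans retinoic acid (ATRA) at 1 µM and doxorubicin at 0.2 µM, alone and in every combination, for 48 h, with DMSO as the vehicle. This gives 8 groups of 2 arrays. Total RNA was extracted with a column kit and labelled with biotin, per the labels' protocols. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

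The authors deposited 1 table of intensities with a detection p-value for each gene and array, and 1 processed table. The deposited intensity table held 34691 gene names with 1 value each per array, on a linear scale from -26 to 22098.4, and 27.5% to 28.2% of the values on an array were below 0, so a background had already been subtracted. How probes were combined into a gene value is not given in the sources used here. The intensities also lay on a shared distribution. Of 1029 distinct signals above 2000 on DMSO replicate 1, 366 (35.6%) occurred again, digit for digit, on a different array. The authors' processed table gave log2 values for 34684 names. They had the same rank order within each array as the intensities (Spearman correlation of 1), a minimum of 6 and medians of 6.609 to 6.61, and equalled the log2 of the signal plus a constant near 89. The submitters' processing notes name limma, without a version.

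Spike-in controls (92) and unnamed expressed sequence clusters (3270) were left out. Genes were kept if their deposited detection p-value was below 0.05 on at least 2 arrays, which left 17126 genes (17123 of them in the authors' log2 table). Of the tested names, 10919 matched a current symbol in the RefSeq gene table of the current human assembly, 2049 matched a single older symbol and 4158 matched none. The names of the file are used throughout. Between 11402 and 12748 genes (36.4% to 40.7%) were detected per array. The detection p-value was a poor guide for some bright genes: of 7142 genes with a mean signal above 100, 117 were detected on fewer than 2 arrays and so were not tested. CDKN1A, with signals of 357.1 to 3433.7, was detected on 4 arrays. ATF3, with a mean signal of 159, was detected on 0 arrays and was not tested.

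Values were corrected with normexp (offset 50), quantile normalized and put on the log2 scale in limma 3.58.1 under R 4.3.3. The plan had named normexp fitted from the detection p-values (offset 16) as the preferred step. That fit gave a background noise SD of 212 to 313, against 7.31 to 7.44 from the negative signals themselves, so the planned fallback was used instead. The fallback's own fit also missed this spread, on the low side, with an SD of 1.52 to 1.85. The switch was decided after the values were seen and before any test was run. The counts under the step named first are given beside each result that it moved by more than 1.5 times.

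All 16 arrays entered a limma fit of group means (lmFit, contrasts and eBayes, 8 residual degrees of freedom), since 2 arrays per group give too little information on the spread alone. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 17 contrasts were each of 7 treatments against DMSO, the 3-drug combination against each pair, departures from the sum of single-drug changes on the log2 scale (additivity), and the average effect of each drug over 8 arrays with and 8 without it. Each error of a log2 change is a standard error (SE), and each SD is over the 2 arrays of a group. The number of arrays limits the precision. Folds are on the scale of the offset signal and understate changes of dim genes. Where every array of the dimmer group had a detection p-value of 0.05 or more and a signal below 22.3 (3 times the noise SD), the fold is given as at least N-fold. It is the bright group's mean against, per array, the higher of the gene's own value and the lowest value among detected genes. The signal limit in this rule was set after the values were seen.

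Shifts of 20 gene lists were tested with camera in limma, at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 20 lists of a comparison. Of these lists, 1 is not reported here, and neither is 1 gene of the fixed set below. The other 19 covered retinoic acid response, homologous recombination and Fanconi repair, the G2/M cell cycle, DNA replication and G1/S, histones, histone deacetylases and chromatin modifiers, apoptosis regulators, mesenchymal genes, epithelial and luminal genes, stem cell and tumour-initiating cell genes, interferon response, inflammatory and NF-kB genes, antigen presentation, neuronal genes, cholesterol synthesis, the unfolded protein and integrated stress response, topoisomerases and anthracycline handling, metallothioneins, and markers of other cell types. The genes named in the text were the largest changes among called members of these lists, the 5 largest rises and 5 largest falls of each comparison among called genes whose 4 arrays separated by group (no such condition for contrasts over more groups), leaving out uncharacterised loci, and a fixed set, of which are reported RARB, CYP26A1, DHRS3, CDKN1A, MDM2, TOP2A, TOP2B, CCNB1, H1F0, HDAC1, HDAC2, CD44, CDH1 and VIM. The lists, this rule, the contrasts and the alternatives were fixed before the data were examined, except where stated.

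The procedure was tested on simulated data with 17126 genes and the real residual spread of each gene. The simulated noise was independent between genes and arrays and held no difference shared by replicate number. For entinostat against DMSO it recovered 85% of 2-fold and 100% of 4-fold changes with 9 false calls. For additivity of entinostat and doxorubicin it recovered 49% and 94% with 9 false calls, for additivity of the 3 drugs 19% and 81% with 5, and for the average effect of ATRA 98% and 100% with 12. In the simulated comparison of entinostat with DMSO, camera found the 1 shifted list and none of the others. Since the simulated genes were independent, this cannot show how often camera calls lists of correlated genes by chance.

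Alternatives were no background correction, median scaling, no filter on dim genes, the authors' table, only the 4 arrays compared, the replicate number as a block, and each array left out in turn. Normexp from the detection p-values and normexp with offset 16 were added after seeing the data, as was the test of gene lists with each array left out. Testing probes singly and the chip as a block were not possible, because the tables give 1 value per gene and no chip. Without an array its group has a lone sample, which is assumed to vary like the other groups.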

Results

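The series asked what expression signatures an epigenetic drug, a differentiating agent and a DNA-damaging drug leave in breast cancer cells, alone and combined. Entinostat inhibits class I histone deacetylases, ATRA activates retinoic acid receptors, and doxorubicin is an anthracycline that poisons topoisomerase II. MDA-MB-231 cells were profiled in 8 groups of 2 arrays: DMSO, each of the 3 drugs, each pair and the 3-drug combination. Between 11402 and 12748 genes were detected per array. Principal component 1 (52.8% of the variance) ran from the arrays of DMSO and ATRA to those with doxorubicin and entinostat together, and component 2 (16.5%) parted entinostat from its absence. Replicates correlated at 0.9807 to 0.9909 across genes, which are not independent replicates. The replicates of doxorubicin alone lay at 4.244 and 21.2 on component 1, and component 3 (6.33%) was positive on every array numbered 1 and negative on every array numbered 2. The main fit did not model this difference by replicate number. Counts that moved with the replicate number as a block are given under the dependence on the processing.

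**Figure D1:**
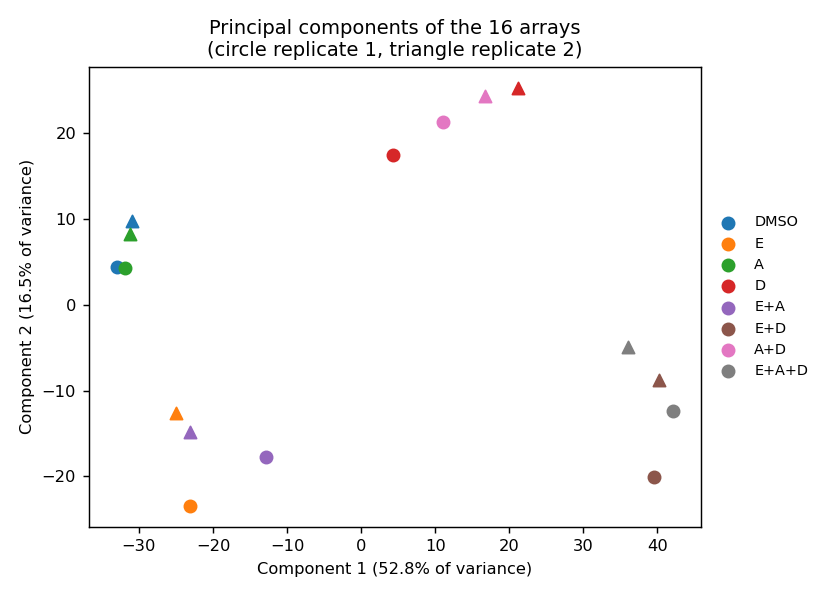
Scores of the 16 arrays on principal components 1 and 2 of the normalized log2 values of all tested genes, with the share of variance on each axis and 1 point per array. The entinostat plus doxorubicin arrays and the 3-drug arrays lie at the far right (scores of 35.98 to 42.11), and the DMSO and ATRA arrays at the far left.

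**Figure D2:**
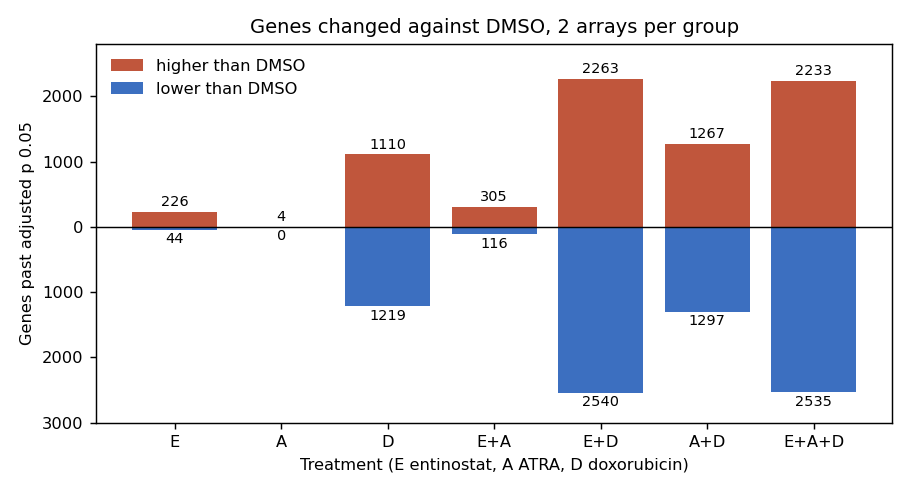
Number of genes called higher and lower (limma, adjusted p below 0.05) in each treatment against DMSO. The pair of entinostat and doxorubicin changed 4803 genes against DMSO and the 3-drug combination 4768, against 4 for ATRA alone.

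Entinostat alone raised epithelial and retinoic acid response genes. CPA4, a carboxypeptidase gene, rose 7.26-fold (log2 change 2.86, SE 0.20, adjusted p = 8.14e-06). CGN, which encodes the tight junction protein cingulin, rose 5.12-fold (2.36, SE 0.14, adjusted p = 1.6e-06), and the LIM-domain gene LMCD1 rose 4.44-fold (2.15, SE 0.16, adjusted p = 1.03e-05). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 4.03-fold (2.01, SE 0.22, adjusted p = 0.000411). CRABP2, which carries retinoic acid to the nucleus, rose 2.90-fold (1.54, SE 0.16, adjusted p = 0.000278). SYT11, a synaptotagmin, rose 6.38-fold (2.67, SE 0.30, adjusted p = 0.000433, and 0.253 with normexp from the detection p-values). Falls were smaller: the cytokine gene CLCF1 fell with a log2 change of -1.02 (SE 0.15, adjusted p = 0.00412), but without entinostat replicate 1 or DMSO replicate 2 the adjusted p was 0.0747 and 0.0715.

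In the list of epithelial and luminal genes, 5 of 19 measured members rose under entinostat and 0 fell (9 and 0 adjusted over the list alone), including the tight junction gene CLDN1 (2.69-fold, adjusted p = 0.000411, and 0.106 with normexp from the detection p-values). The list shifted up (camera adjusted p = 5.55e-07, and 0.0331 with an estimated correlation). In the retinoic acid response, 3 of 16 members rose and 0 fell (4 and 0 adjusted over the list alone), and the shift also held (8.36e-05, and adjusted p = 0.0331 with an estimated correlation). DNA replication and G1/S genes shifted down (median log2 change -0.25, camera adjusted p = 0.000101) with 0 of 29 members called, also adjusted over the list alone, adjusted p = 0.236 with an estimated correlation, and 0.214 without entinostat replicate 1. Neuronal genes shifted up with 2 of 14 members rising (4 adjusted over the list alone, camera adjusted p = 0.00604, and adjusted p = 0.0706 with an estimated correlation). Mesenchymal genes shifted the same way, with 1 of 24 rising (5 adjusted over the list alone, 0.0107, and adjusted p = 0.172 with an estimated correlation), and so did markers of blood, endothelium and fibroblasts, with 0 of 10 called (0 adjusted over the list alone, 0.0107, adjusted p = 0.156 with an estimated correlation, and 0.214 without entinostat replicate 1).

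In total, limma called 270 of 17126 genes under entinostat, 226 higher and 44 lower. The count was 67 without DMSO replicate 1, 26 without entinostat replicate 1 and 37 without DMSO replicate 2, and 129 (87 higher, 42 lower) with normexp from the detection p-values.

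ATRA alone changed few genes. DHRS3, a retinaldehyde reductase induced by retinoic acid, averaged 9.178 on the log2 scale (SD 0.032, n = 2) against 6.563 (SD 0.14, n = 2) in DMSO, a 6.13-fold rise (2.61, SE 0.31, adjusted p = 0.0141). TGM2, the transglutaminase induced by retinoids, rose 2.57-fold (1.36, SE 0.18, adjusted p = 0.0181), and IGFBP6, an insulin-like growth factor binding protein, had a log2 change of 1.42 (adjusted p = 0.0429). The remaining called gene was C9ORF169, an uncharacterised name given here after its values were seen. In the retinoic acid response list, 2 of 16 members rose and 0 fell (4 and 0 adjusted over the list alone), with camera adjusted p = 1.92e-10 and 0.0027 with an estimated correlation. With all arrays, none of the other lists passed under ATRA, the lowest camera adjusted p being that of the metallothioneins (0.0737). With an array left out some did, such as antigen presentation without ATRA replicate 1 and the metallothioneins without ATRA replicate 2. The replicate numbers are then unbalanced, so a difference shared by replicate number can mix into these shifts. Of the canonical targets, RARB lay near background and was not called under ATRA (0.11, SE 0.11, adjusted p = 1), and CYP26A1 was detected on 0 arrays and was not tested.

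Limma called 4 genes under ATRA, all higher, and 470 had an unadjusted p below 0.05. With any of the 4 arrays (DMSO replicates 1 and 2, ATRA replicates 1 and 2) left out the count was 0, and the adjusted p of DHRS3 was 0.131, 0.162, 0.324 and 0.193, in that order. For TGM2 it lay between 0.162 and 0.441 and for IGFBP6 between 0.131 and 0.919. The count was 0 with normexp from the detection p-values (DHRS3 adjusted p = 0.929), 1 with offset 16, 2 in the authors' table and 10 with only the 4 arrays.

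Doxorubicin alone raised ID2, an inhibitor of basic helix-loop-helix factors, 9.81-fold (3.29, SE 0.32, adjusted p = 6.26e-05), and HES4, of the Hairy/Enhancer-of-split family, rose 6.58-fold (2.72, SE 0.22, adjusted p = 3.77e-05). FOSB, an AP-1 subunit, rose 12.4-fold (3.63, SE 0.56, adjusted p = 0.00106, and 0.104 with normexp from the detection p-values). The carbonic anhydrase gene CA2 rose at least 4.74-fold (adjusted p = 3.77e-05, and 0.0585 with that setting). BCAR3, an adaptor of Src-family signalling, fell with a log2 change of -2.30 (SE 0.27, adjusted p = 0.000185), and the translation factor gene EIF4A2 with -2.10 (SE 0.26, adjusted p = 0.000277). CDKN1A rose 4.51-fold (2.17, SE 0.22, adjusted p = 8.04e-05).

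Of 16 antigen presentation genes, 6 rose and 0 fell under doxorubicin (8 and 0 adjusted over the list alone), among them the peptide transporter TAP1 (4.77-fold, adjusted p = 0.000112) and HLA-E (2.91-fold, adjusted p = 6.26e-05). The list shifted up (camera adjusted p = 3.37e-06, and adjusted p = 0.374 with an estimated correlation). Of 30 G2/M genes, 12 fell and 0 rose (21 and 1 adjusted over the list alone), among them the cyclin gene CCNA2 (-1.18, SE 0.21, adjusted p = 0.00246), and the list shifted down (4.61e-08, and adjusted p = 0.374 with an estimated correlation). CCNB1, the mitotic cyclin, fell with -1.56 (adjusted p = 0.00569), and its adjusted p was 0.0885 without DMSO replicate 1 and 0.0715 with normexp from the detection p-values. Of 6 metallothioneins, which bind zinc and copper, 3 fell and 0 rose (4 and 0 adjusted over the list alone), MT1E with -1.53 (adjusted p = 0.00096), and the list shifted down (0.000667, and adjusted p = 0.374 with an estimated correlation). Of 21 inflammatory and NF-kB genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone), including SOD2 (2.52-fold, adjusted p = 0.000357), with camera adjusted p = 0.00616 and adjusted p = 0.374 with an estimated correlation.

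Among 15 topoisomerase and anthracycline-handling genes, 5 rose and 2 fell (the same counts adjusted over the list alone) with no shift of the list (camera adjusted p = 0.437). The carbonyl reductase CBR3 rose 2.40-fold (adjusted p = 0.00141) and the aldo-keto reductase AKR1B1 rose 2.30-fold (adjusted p = 0.000251). Of 15 histone genes, 2 fell and 0 rose (the same adjusted over the list alone), while the median was 0.28 and the list did not shift (camera adjusted p = 0.69). H2AFX, which encodes the histone variant phosphorylated at DNA breaks, fell with -0.87 (adjusted p = 0.00159). The linker histone gene H1F0 fell with -2.09 (adjusted p = 0.0043, and 0.0551 without doxorubicin replicate 2). The smooth muscle actin gene ACTA2, in the list of other cell types, rose 4.40-fold (2.14, SE 0.39, adjusted p = 0.00287, and 0.141 with normexp from the detection p-values).

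Limma called 2329 genes under doxorubicin, 1110 higher and 1219 lower. The count was 917 without DMSO replicate 1, 1349 without DMSO replicate 2, 1074 without doxorubicin replicate 2 and 1030 with only the 4 arrays, and 681 genes were called higher with normexp from the detection p-values.

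Entinostat with ATRA raised CPA4 14.3-fold (3.84, SE 0.20, adjusted p = 3.08e-07) and CGN 5.33-fold (2.42, SE 0.14, adjusted p = 5.76e-07). DHRS3 rose 5.73-fold (2.52, SE 0.31, adjusted p = 0.000704, and 0.0607 with normexp from the detection p-values). CRABP2 rose 4.03-fold (2.01, SE 0.16, adjusted p = 1.42e-05), ELF3, an epithelial ETS factor, 3.46-fold (1.79, SE 0.22, adjusted p = 0.000579), and CYP26B1, which degrades retinoic acid, 2.54-fold (1.34, SE 0.16, adjusted p = 0.000534). The keratin gene KRT81 rose 8.05-fold (adjusted p = 0.00459, but 0.0658 without DMSO replicate 1 and 0.0588 with normexp from the detection p-values). BMI1, a polycomb gene of self-renewing cells, fell with -1.37 (adjusted p = 0.00412, and 0.0741 without DMSO replicate 1).

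In the retinoic acid response, 5 of 16 members rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 3.64e-13 and 0.00128 with an estimated correlation. Of 19 epithelial and luminal genes, 7 rose and 0 fell (10 and 1 adjusted over the list alone), including the claudin gene CLDN7 (3.44-fold, adjusted p = 0.00266), with camera adjusted p = 3.51e-08 and 0.0248 with an estimated correlation. Of 30 G2/M genes, 4 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 change of -0.60, camera adjusted p = 2.06e-14 and adjusted p = 0.142 with an estimated correlation. This fall was larger on replicate 1 of the treatment, with a median of -0.90 and 12 members falling without its replicate 2, and a median of -0.39 and 0 falling without its replicate 1 (camera adjusted p = 1.23e-06). Without DMSO replicates 1 and 2 in turn, 0 and 2 members fell. The mitotic kinase gene AURKA fell with -1.36 (adjusted p = 0.0137), and its adjusted p was 0.163 without DMSO replicate 1, 0.179 without entinostat plus ATRA replicate 1, 0.0532 with only the 4 arrays and 0.0585 with normexp from the detection p-values. Of 21 inflammatory genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone), IL1A by at least 3.29-fold (adjusted p = 0.0014, and 0.0816 with normexp from the detection p-values), with camera adjusted p = 5.47e-07 and adjusted p = 0.0763 with an estimated correlation. The class II antigen-loading gene HLA-DMB rose 2.80-fold (adjusted p = 0.00046). Of the 10 markers of other cell types, 0 passed (0 adjusted over the list alone), while the list shifted up (0.016, adjusted p = 0.142 with an estimated correlation, 0.0554 without entinostat plus ATRA replicate 1, and 0.0717 without DMSO replicate 2).

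Limma called 421 genes under entinostat with ATRA, 305 higher and 116 lower. The count was 124 without DMSO replicate 1, 125 without entinostat plus ATRA replicate 1, 134 without DMSO replicate 2 and 277 (142 higher, 135 lower) with normexp from the detection p-values, and the split was 279 higher and 54 lower with only the 4 arrays.

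Entinostat with doxorubicin gave the broadest response of the pairs. The cysteine protease gene CTSL2 rose at least 36.8-fold (adjusted p = 1.23e-06), ZCCHC12 at least 25-fold (adjusted p = 2e-05) and HAND1, a basic helix-loop-helix factor, at least 18.1-fold (adjusted p = 1.26e-06). SYT11 rose 22.2-fold (4.47, SE 0.30, adjusted p = 4.12e-07) and FOSB 21.8-fold (4.44, SE 0.56, adjusted p = 5.39e-05). The largest falls under the naming rule were those of the kinase gene CDK6, which drives cells into S phase (-2.86, SE 0.24, adjusted p = 2.38e-06), BCAR3 (-2.82, SE 0.27, adjusted p = 5.98e-06), PHLDA1 (-2.68, SE 0.34, adjusted p = 6e-05), PLAU, the urokinase plasminogen activator (-2.54, SE 0.45, adjusted p = 0.000727), and MYEOV (-2.34, SE 0.15, adjusted p = 3.22e-07).

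**Figure D3:**
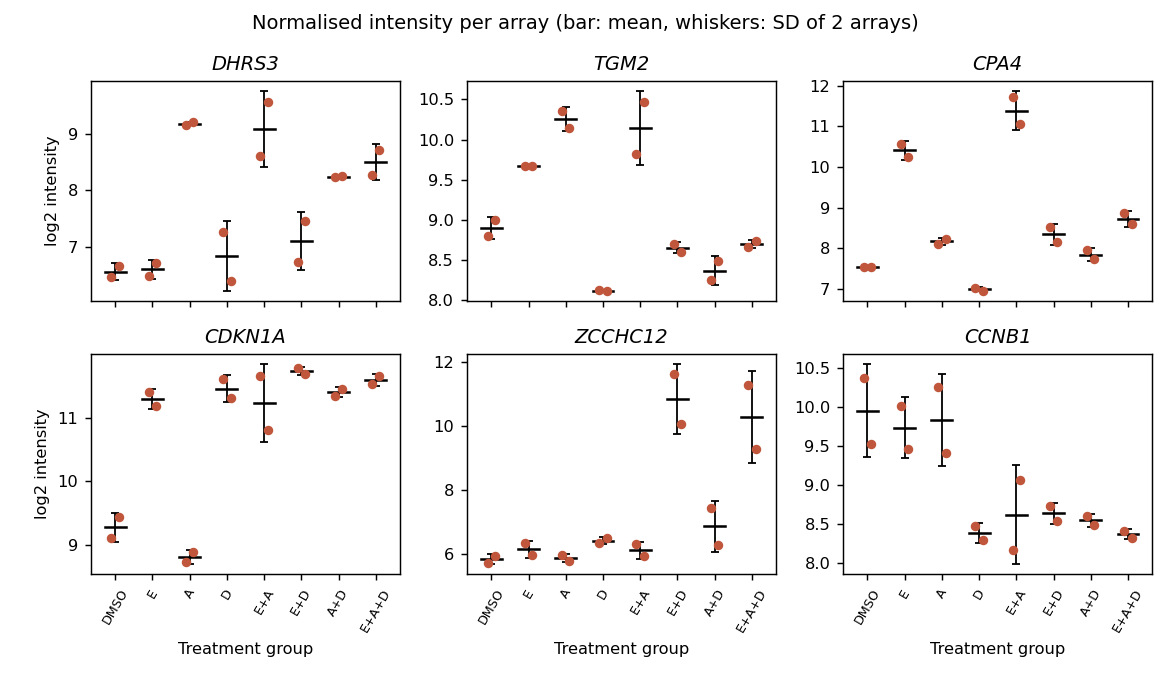
Normalized log2 values of named genes on each of the 16 arrays, by treatment, with 1 point per array and the group mean. CDKN1A is higher in all 6 groups with entinostat or doxorubicin than in DMSO, while DHRS3 is high on the arrays with ATRA.

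Of 24 interferon-response genes, 13 rose and 0 fell under this pair (the same adjusted over the list alone). The interferon regulatory factor IRF7 rose 8.73-fold (3.13, SE 0.34, adjusted p = 1.7e-05) and the chemokine gene CXCL10 at least 8.87-fold (adjusted p = 3.68e-05). The list shifted up (camera adjusted p = 2.35e-05, and adjusted p = 0.117 with an estimated correlation). Of 16 antigen presentation genes, 9 rose and 0 fell (the same adjusted over the list alone), including HLA-B (7.99-fold, adjusted p = 0.00029) and TAP1 (4.40-fold, adjusted p = 2.42e-05), with camera adjusted p = 1.11e-05 and adjusted p = 0.204 with an estimated correlation. Of 21 inflammatory genes, 12 rose and 2 fell (13 and 4 adjusted over the list alone), with 0.000653 and adjusted p = 0.174 with an estimated correlation. In cholesterol synthesis, 10 of 20 genes rose and 1 fell (the same adjusted over the list alone), HMGCS1, which makes the mevalonate precursor, by 5.68-fold (2.51, SE 0.39, adjusted p = 0.000272), with 0.000319 and adjusted p = 0.161 with an estimated correlation. Retinoic acid response genes rose in 9 of 16 cases and fell in 1 (the same adjusted over the list alone), CRABP2 by 10.1-fold (3.34, SE 0.16, adjusted p = 2.04e-08), with 0.000239 and adjusted p = 0.0772 with an estimated correlation. Of the epithelial genes, 7 of 19 rose and 0 fell (10 and 0 adjusted over the list alone), CGN by 8.43-fold and CLDN1 by 7.47-fold (adjusted p = 2.04e-08 and 6.49e-08), with 9.74e-05 and adjusted p = 0.109 with an estimated correlation.

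Of 21 homologous recombination and Fanconi genes, 11 fell and 0 rose (12 and 0 adjusted over the list alone). NBN, a subunit of the break-sensing MRN complex, was at least 2.71-fold lower (adjusted p = 4.73e-06), and the checkpoint kinase gene CHEK1 fell with -0.96 (SE 0.22, adjusted p = 0.00388). The list shifted down (camera adjusted p = 0.000988, and adjusted p = 0.204 with an estimated correlation). Of 30 G2/M genes, 15 fell and 2 rose (19 and 3 adjusted over the list alone), CCNA2 with -1.74 (adjusted p = 4.08e-05), with 0.000106 and adjusted p = 0.376 with an estimated correlation. CDKN1A rose 5.45-fold (2.45, SE 0.22, adjusted p = 3.85e-06) and the antiproliferative gene BTG2 rose 3.26-fold (adjusted p = 0.000159). Apoptosis regulators went both ways, 4 of 23 up and 4 down (the same adjusted over the list alone), without a shift of the list (camera adjusted p = 0.714). The transcriptional repressor BCL6 rose 3.66-fold (adjusted p = 2.44e-05) and the anti-apoptotic gene BCL2L1 fell with -1.38 (adjusted p = 6.91e-05). Of 21 histone deacetylases and chromatin modifiers, 2 rose and 4 fell (the same adjusted over the list alone), without a shift (camera adjusted p = 0.438), among them the histone methyltransferase SUV39H1 (-1.20, adjusted p = 4.01e-05) and the DNA methyltransferase DNMT1 (-0.98, adjusted p = 0.000783). In the unfolded protein and integrated stress response, 4 of 15 rose and 1 fell (5 and 1 adjusted over the list alone), CEBPB by 2.79-fold (adjusted p = 0.000197), with 0.0419, adjusted p = 0.376 with an estimated correlation, 0.12 without the pair's replicate 1 and 0.174 without DMSO replicate 2.

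Of the 10 markers of other cell types, 3 rose and 1 fell under entinostat with doxorubicin (4 and 1 adjusted over the list alone), ACTA2 by 8.23-fold (3.04, SE 0.39, adjusted p = 6.42e-05), and the list shifted up (camera adjusted p = 0.0362, adjusted p = 0.174 with an estimated correlation, 0.0587 without DMSO replicate 2, and 0.0511 without the pair's replicate 2). Limma called 4803 genes, 2263 higher and 2540 lower.

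ATRA with doxorubicin raised FOSB 15.6-fold (3.96, SE 0.56, adjusted p = 0.000484, and 0.0562 with normexp from the detection p-values), ID2 10.7-fold (3.42, SE 0.32, adjusted p = 3.43e-05), the histone chaperone gene ASF1B 6.17-fold (2.63, SE 0.18, adjusted p = 8.3e-06) and HES4 5.66-fold (2.50, SE 0.22, adjusted p = 2.71e-05). BCAR3 fell with -2.43 (SE 0.27, adjusted p = 0.000101), EIF4A2 with -2.18 (SE 0.26, adjusted p = 0.000177) and CCDC106 with -1.98 (SE 0.30, adjusted p = 0.000759). DHRS3 rose 3.19-fold (1.68, SE 0.31, adjusted p = 0.00289, and 0.327 with normexp from the detection p-values). Retinoic acid response genes rose in 5 of 16 cases and fell in 0 (8 and 2 adjusted over the list alone), with camera adjusted p = 0.00623 and adjusted p = 0.213 with an estimated correlation. Of 30 G2/M genes, 13 fell and 1 rose (17 and 1 adjusted over the list alone, camera adjusted p = 1.35e-06, and adjusted p = 0.48 with an estimated correlation), and of 16 antigen presentation genes 6 rose and 0 fell (the same adjusted over the list alone, 1.48e-05, and adjusted p = 0.48 with an estimated correlation).

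Limma called 2564 genes under ATRA with doxorubicin, 1267 higher and 1297 lower. The count was 1042 without DMSO replicate 1, 1495 without DMSO replicate 2, 1525 without ATRA plus doxorubicin replicate 1 and 1126 without ATRA plus doxorubicin replicate 2, and 839 genes were called higher with normexp from the detection p-values.

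The 3-drug combination raised the protease gene CTSL2 at least 26.7-fold (adjusted p = 2.87e-06), FOSB 26.3-fold (4.72, SE 0.56, adjusted p = 3.6e-05), the noncoding transcript HCP5 of the major histocompatibility region 17.2-fold (4.10, SE 0.15, adjusted p = 1.51e-09) and SYT11 17.2-fold (4.10, SE 0.30, adjusted p = 1.12e-06). BCAR3 fell with -2.74 (SE 0.27, adjusted p = 8.19e-06), PHLDA1 with -2.48, CDK6 with -2.47, EIF4A2 with -2.37 and the mitotic kinesin gene KIF20B with -2.35 (adjusted p = 2.55e-05). In the retinoic acid response, 11 of 16 members rose and 1 fell (12 and 1 adjusted over the list alone), CRABP2 by 10.1-fold (3.34, SE 0.16, adjusted p = 3.34e-08) and the retinoid-induced growth suppressor RARRES3 by 4.69-fold (2.23, SE 0.34, adjusted p = 0.000224), with camera adjusted p = 1.13e-05 and 0.0248 with an estimated correlation. Of 21 repair genes, 9 fell and 0 rose (the same adjusted over the list alone, 0.00276, and adjusted p = 0.234 with an estimated correlation). Interferon genes rose in 12 of 24 cases and fell in 0 (13 and 0 adjusted over the list alone, 2.83e-05, and adjusted p = 0.174 with an estimated correlation).

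Of 20 stem cell and tumour-initiating cell genes, 6 rose and 3 fell under the 3 drugs (the same adjusted over the list alone), with a median of 0.081, a mean of -0.019 and no shift (camera adjusted p = 0.682). BMI1 fell with -1.80 (SE 0.22, adjusted p = 4.68e-05), and CD44, the hyaluronan receptor used to sort tumour-initiating cells, fell with -0.71 (SE 0.17, adjusted p = 0.00602, and 0.0979 without 3-drug replicate 1). TOP2A, which encodes a form of the topoisomerase II that doxorubicin poisons, fell with -0.98 (SE 0.17, adjusted p = 0.000589), and CCNB1 with -1.58 (SE 0.32, adjusted p = 0.00204). HDAC1 fell with -0.42 (adjusted p = 0.0301), but its adjusted p was 0.0803 with offset 16, 0.0648 with only the 4 arrays, 0.189 without DMSO replicate 1, and 0.176 and 0.0516 without 3-drug replicates 1 and 2. HDAC2 (0.09, adjusted p = 0.70), TOP2B (-0.49, adjusted p = 0.0624) and VIM (-0.20, adjusted p = 0.285) were not called. CDH1, the E-cadherin gene, was detected on 1 array and was not tested, and MDM2, near background, was not called (-0.06, adjusted p = 0.768). Limma called 4768 genes, 2233 higher and 2535 lower, and 3155 without DMSO replicate 1.

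**Figure D4:**
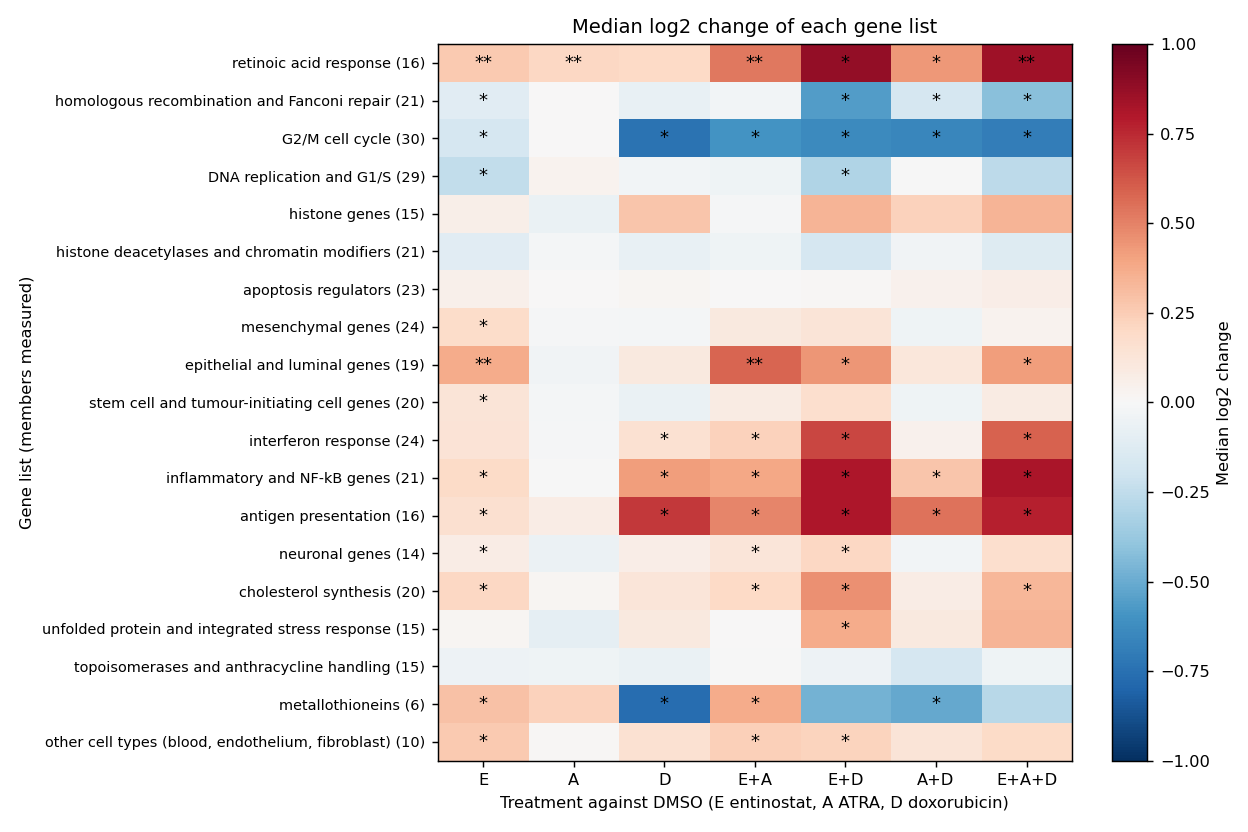
Median log2 change of 19 gene lists against DMSO for the 7 treatments (colour, from -1 to 1), with the number of measured members beside each name, * for a camera adjusted p below 0.05 and ** where it also held with an estimated correlation. The retinoic acid list is the row in which most treatments carry **, and it did so in 4 of the 7.

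Adding entinostat to ATRA and doxorubicin raised HCP5 12.8-fold (3.68, SE 0.15, adjusted p = 6.81e-09), the stress gene DDIT4L 7.93-fold (2.99, SE 0.23, adjusted p = 8.11e-06), HAND1 6.93-fold (2.79, SE 0.34, adjusted p = 0.000425) and CTSL2 6.55-fold (2.71, SE 0.40, adjusted p = 0.00156). CLCF1 fell with -1.16 (SE 0.15, adjusted p = 0.000575). The extracellular matrix gene RELN fell with -1.55 (adjusted p = 0.0148), and its adjusted p was 0.182 without ATRA plus doxorubicin replicate 1, 0.108 without 3-drug replicate 2 and 0.102 with normexp from the detection p-values. Of 16 retinoic acid response genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with camera adjusted p = 3.4e-05 and 0.0368 with an estimated correlation. Of 19 epithelial genes 7 rose and 0 fell (the same adjusted over the list alone, 2.71e-06, and adjusted p = 0.0508 with an estimated correlation), and of 24 interferon genes 6 rose and 0 fell (8 and 0 adjusted over the list alone, 2.71e-06, and adjusted p = 0.085 with an estimated correlation). Limma called 1098 genes, 616 higher and 482 lower. The count was 211 without ATRA plus doxorubicin replicate 1, 272 without 3-drug replicate 1, 546 without ATRA plus doxorubicin replicate 2 and 646 without 3-drug replicate 2, and 649 (385 higher, 264 lower) with normexp from the detection p-values and 698 (471 higher, 227 lower) with only the 4 arrays.

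Adding ATRA to entinostat and doxorubicin left DHRS3 with a log2 difference of 1.4 (SE 0.31), which did not pass (adjusted p = 1). Limma called 0 genes, with 400 (2.34%) at an unadjusted p below 0.05. Cholesterol synthesis shifted down with 0 of 20 members called (0 adjusted over the list alone, median -0.14, camera adjusted p = 0.0183, and adjusted p = 0.384 with an estimated correlation).

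Adding doxorubicin to entinostat and ATRA raised FOSB 21.7-fold (4.44, SE 0.56, adjusted p = 0.000137), VASN, a cell-surface binder of transforming growth factor beta, 16.1-fold (4.01, SE 0.31, adjusted p = 5.13e-06) and CTSL2 11.9-fold (3.57, SE 0.40, adjusted p = 6.32e-05). The matricellular gene CYR61 fell with -3.20 (SE 0.31, adjusted p = 2.64e-05), CPA4 with -2.66 (SE 0.20, adjusted p = 4.93e-06), the Wnt antagonist DKK1 with -2.33 (SE 0.22, adjusted p = 2.11e-05) and the AP-1 subunit gene FOSL1 with -2.26 (SE 0.26, adjusted p = 7.04e-05). Limma called 3341 genes, 1576 higher and 1765 lower, and 1947 without 3-drug replicate 1 and 1757 without entinostat plus ATRA replicate 2.

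Additivity was tested on the log2 scale. Under entinostat with doxorubicin, RGS16, a regulator of G-protein signalling, exceeded the sum of the single-drug changes by 2.33 (SE 0.28, adjusted p = 0.00176, and 0.092 with normexp from the detection p-values) and DDIT4L by 2.39 (SE 0.32, adjusted p = 0.00545, and 0.0543 without DMSO replicate 2 and 0.0705 with that normexp). CDKN1A fell short of the sum, with a departure of -1.74 (SE 0.31, adjusted p = 0.0334), since each drug alone raised it about as far as both did. Limma called 40 genes, 35 above and 5 below the sum. Leaving out an array gave 10 (DMSO replicate 1), 10 (DMSO replicate 2), 23 (entinostat replicate 1), 12 (entinostat replicate 2), 17 (doxorubicin replicate 1), 137 (doxorubicin replicate 2), 25 (the pair's replicate 1) and 91 (the pair's replicate 2). The adjusted p of CDKN1A was 0.197 and 0.0901 without DMSO replicates 1 and 2, 0.128 and 0.102 without entinostat replicates 1 and 2, 0.124 without doxorubicin replicate 1, 0.0869 and 0.0569 without the pair's replicates 1 and 2, 0.0654 with offset 16 and 0.0705 with normexp from the detection p-values.

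For entinostat with ATRA and for ATRA with doxorubicin, limma called 0 genes departing from additivity, with 304 and 440 at an unadjusted p below 0.05. Under the 3 drugs, 4 genes exceeded the sum of the 3 single changes: CYP27B1, the vitamin D 1-alpha-hydroxylase (2.07, SE 0.28, adjusted p = 0.0323), HCP5 (1.95, SE 0.29, adjusted p = 0.0436), the melanosome gene SILV (1.94, SE 0.27, adjusted p = 0.0323) and SEPX1, a methionine sulfoxide reductase (1.76, SE 0.26, adjusted p = 0.0436). The count was 0 with offset 16 and 0 without DMSO, entinostat, ATRA, doxorubicin or 3-drug replicate 1, or DMSO or entinostat replicate 2. It was 1 without ATRA replicate 2, 17 without doxorubicin replicate 2 and 7 without 3-drug replicate 2. Without background correction HCP5 (adjusted p = 0.117) and SEPX1 (adjusted p = 0.0621) were lost, and CYP27B1 had an adjusted p of 0.186 with normexp from the detection p-values. For SILV the adjusted p reached 0.631, without DMSO replicate 2.

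Averaged over the other drugs, with 8 arrays against 8, entinostat raised SYT11 6.80-fold (2.77, SE 0.15, adjusted p = 3.51e-08), HCP5 6.79-fold (2.76, SE 0.073, adjusted p = 2.42e-11) and DDIT4L 4.64-fold (2.22, SE 0.11, adjusted p = 2.57e-08). CLCF1 fell with -1.14 (SE 0.075, adjusted p = 2.68e-07) and the lymphangiogenic factor gene VEGFC with -0.87 (SE 0.078, adjusted p = 4.05e-06). Limma called 3977 genes, 1876 higher and 2101 lower. Of 29 DNA replication genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 7.19e-05, and adjusted p = 0.226 with an estimated correlation). Of 19 epithelial genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone, 3.58e-07, and 0.0306 with an estimated correlation). Mesenchymal genes shifted up with them, 7 of 24 rising and 0 falling (7 and 1 adjusted over the list alone, 0.0244, and adjusted p = 0.181 with an estimated correlation), and so did markers of other cell types, 4 of 10 rising and 0 falling (5 and 0 adjusted over the list alone, 0.00967, and adjusted p = 0.0843 with an estimated correlation).

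The average effect of ATRA was 3.93-fold on DHRS3 (1.98, SE 0.16, adjusted p = 8.19e-05, and 0.152 with normexp from the detection p-values), 2.46-fold on PTGES, the prostaglandin E synthase (1.30, SE 0.18, adjusted p = 0.0101, and 0.0625 with that normexp), and 1.78-fold on TINAGL1 (0.84, SE 0.081, adjusted p = 0.000362). ELF3 rose 1.99-fold (0.99, SE 0.11, adjusted p = 0.00119, and 0.248 with that normexp). Limma called 19 genes, 18 higher and 1 lower. The count was 2 with normexp from the detection p-values, 8 without DMSO replicate 1, 11 without entinostat replicate 1, 10 without entinostat plus doxorubicin replicate 1, 12 without entinostat replicate 2, 11 without ATRA replicate 2 and 10 without 3-drug replicate 2. The retinoic acid list shifted up (4 of 16 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 1.87e-10, and 0.00269 with an estimated correlation).

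The average effect of doxorubicin was 17.8-fold on FOSB (4.16, SE 0.28, adjusted p = 6.16e-08), 9.82-fold on ID2 (3.30, SE 0.16, adjusted p = 5.59e-09), 8.72-fold on VASN (3.12, SE 0.15, adjusted p = 5.59e-09) and 6.58-fold on ULBP2, a ligand of the NKG2D receptor (2.72, SE 0.14, adjusted p = 6.19e-09). CYR61 fell with -2.58 (SE 0.16, adjusted p = 3.12e-08). H1F0 fell with -1.94 (adjusted p = 3.27e-06) and CCNB1 with -1.05 (adjusted p = 9.84e-05). Limma called 7047 genes, 3391 higher and 3656 lower.

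Each drug's changes alone were set against its changes on top of the other drugs, in contrasts whose group means share no array. Both contrasts use the same estimate of each gene's spread, so their calls are not fully independent, as the expected counts assume. Doxorubicin raised 710 genes in both, against 102 expected of independent lists, and lowered 853, against 126. Entinostat raised 112 in both, against 8.13 expected, and lowered 20, against 1.24. For ATRA 0 genes were called on top of the other drugs, so the overlap was fixed at 0. Of the 4 genes called under ATRA alone, 4 kept their direction on top, but a kept direction does not show a kept effect. TGM2 lay at 8.656 and 8.728 with the 3 drugs, and at 8.702 and 8.6 with entinostat and doxorubicin. DHRS3 lay at 8.274 and 8.718, against 6.735 and 7.462. Across genes, which are not independent replicates, the log2 changes correlated at 0.731 for doxorubicin, 0.484 for entinostat and 0.0516 for ATRA.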

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

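The tests of explanations in this part were chosen after the results were seen, while the additivity contrasts, the average effects and the arrays left out were planned. The departures from additivity were singled out because the effect of a drug differed with the other drugs present, by a test of the difference itself. The small count of ATRA alone is weighed beside them and was not singled out by such a test.

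Under entinostat with doxorubicin, 40 genes departed from the sum of the single-drug log2 changes. The largest positive departures were ZCCHC12 (4.12), FAM90A7 (2.82), DDIT4L (2.39), RGS16 (2.33) and GSTM3 (2.31). Of these, only RGS16 was called with each of the 8 arrays left out, and DDIT4L was lost without DMSO replicate 2 (adjusted p = 0.0543). Negative departures were CDKN1A (-1.74), CPA4 (-1.51), BASP1 (-1.13), TLE1 (-1.08) and FAM69A (-1.08). Under the 3 drugs the 4 departures were CYP27B1 (2.07), HCP5 (1.95), SILV (1.94) and SEPX1 (1.76).

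For the 35 genes above additivity, chance error of the 8 arrays was tested in the 8 other arrays, which all held ATRA. There the median departure was 1.24, against 1.60 in the arrays that chose them, and 34 of 35 were positive, which argues against chance error as the whole source. On linear signals 35 of 35 also exceeded the sum, which was largely fixed where both single changes went the same way. Of the genes whose single changes went opposite ways, 11 of 11 exceeded it, which argues against the log2 scale for these and leaves it open for the others. ZCCHC12 lay at 9.273 to 11.62 on the 4 arrays with both drugs and at most at 7.423 on the 12 others, so a combined action of both drugs stays a hypothesis, found and tested on the same data.

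CDKN1A fell short of the sum. A ceiling of the scanner was argued against by 464 tested genes that were brighter than the 4619 that linear additivity needed, where CDKN1A reached 3334. The departure was also present on the linear scale (-1285, SE 386), which argues against the log2 scale as the whole source. In the 8 arrays with ATRA the log2 departure was -2.22 (SE 0.31), which argues against chance error. How probes were combined into its value is not given in the sources used here, so a ceiling of a probe was not tested, and neither was a shared upper limit of its induction.

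ATRA alone changed 4 genes. Arrays labelled ATRA that held untreated cells were argued against by DHRS3, whose lowest ATRA array lay 2.49 log2 units above the highest DMSO array. Whether 2 arrays per group hid many changes of over 2-fold could not be told. In limma 470 (2.74%) had an unadjusted p below 0.05, a share below the 0.05 that no change would give. With the replicate number as a block 631 did and 10 genes were called, so a large error in the main fit may lower this share. In simulated data the comparison of entinostat with DMSO, of the same size, recovered 85% of 2-fold changes. The simulated noise was independent and held no difference shared by replicate number, so this recovery may not hold here. Changes of dim genes are also understated. In the average effect over 8 against 8 arrays 3 genes were called at over 2-fold, but this average dilutes changes present with ATRA alone, as for TGM2, with 1.36 alone and 0.53 on average.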

How the results depend on the processing

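The number of genes called depended on the alternatives below, and the cause was not tested. Total counts not given here moved by 1.5 times or less. For entinostat the count was 129 with normexp from the detection p-values, and 26 to 180 with an array left out, and its genes called lower were 22 with only the 4 arrays and 20 with offset 16. For ATRA it was 2 in the authors' table, 0 with normexp from the detection p-values, 1 with offset 16, 10 with only the 4 arrays compared, and 0 without any of its arrays. Doxorubicin gave 1030 with only the 4 arrays, 917 to 2525 with an array left out, and 681 higher with normexp from the detection p-values. Entinostat with ATRA gave 277 with normexp from the detection p-values, 124 to 351 with an array left out, and 63 lower with offset 16, ATRA with doxorubicin 1042 to 1525, and 839 higher with normexp from the detection p-values, and the 3 drugs 3155 to 3794. Entinostat on top of the other drugs gave 649 with normexp from the detection p-values, 698 with only the 4 arrays, 297 lower with offset 16, and 211 to 646 with an array left out, and doxorubicin on top of the others 1757 to 2536. Departures from additivity numbered 10 to 137 for entinostat with doxorubicin with an array left out, and for the 3 drugs 0 with offset 16 and 0 to 17 with an array left out. The average effect of ATRA gave 2 with normexp from the detection p-values, and 8 to 26 with an array left out. Of the 58 gene list shifts against DMSO, 6 held with an estimated correlation. This correlation was estimated without the replicate number as a block, so a difference shared by replicate number may be part of it. An estimated correlation with the block was not run. The rule used here took the replicate numbers as pairs only if all 28 correlations of deviations between groups exceeded 0.1. Of these, 26 did (0.019 to 0.42), but all 28 were above 0, with a median of 0.22. Component 3 also parted every array numbered 1 from every array numbered 2. A difference shared by replicate number was thus present, and the main fit left it in its error. With an array left out, this difference can also mix into the contrast. With the replicate number as a block, entinostat gave 546, ATRA 10, entinostat with ATRA 800, entinostat on top of the others 1875, additivity of entinostat and doxorubicin 111, the average effect of ATRA 32, and entinostat called alike alone and on top 271 instead of 132. List shifts against DMSO then numbered 65, the 58 among them, and those gained were interferon response under entinostat (0.0284) and under ATRA with doxorubicin (0.0368), metallothioneins under ATRA (0.0426), retinoic acid response under doxorubicin (0.0347), histone genes under entinostat with doxorubicin (0.0324), and DNA replication (0.0496) and neuronal genes (0.0485) under the 3 drugs. Probes singly and the chip as a block were not run.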

Other observations

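The counts over other splits and the test on genes at background were planned before their results were seen. The noncoding genes below, the test on genes at background without the filter, and the splits between arrays alike in the other drugs were chosen after their values were seen.

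A few small noncoding RNAs changed with doxorubicin, in both directions, and were not tested as a group. RPPH1, the RNA component of ribonuclease P, fell on average over the other drugs with -2.12 (SE 0.18, adjusted p = 4.54e-07), and against DMSO it fell under doxorubicin alone (-2.43, adjusted p = 0.00081, and 0.0549 with normexp from the detection p-values). SNORD104 (-0.83, SE 0.12, adjusted p = 4.31e-05) and SNORA61 (-0.66, SE 0.16, adjusted p = 0.00359), which guide modification of ribosomal RNA, also fell on average. SNORD13 (1.75, SE 0.35, adjusted p = 0.000985) and RNU4-2, the U4 spliceosomal RNA (0.85, SE 0.15, adjusted p = 0.000363), rose. RN7SK, which holds the elongation factor P-TEFb inactive, was not called (0.64, SE 0.27, adjusted p = 0.0719).

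A hypothesis written before the test held that entinostat would raise a larger share of genes at background, relative to its share over all genes, than doxorubicin does. Of 3101 genes at background without entinostat, 317 (10.2%) were called higher in its average effect, against 11% of all genes, a ratio of 0.933. For doxorubicin it was 435 of 3374 (12.9% against 19.8%), a ratio of 0.651. The filter on detected genes bears on both ratios, since a gene at background without a drug was kept largely if it was detected with it. Without the filter they were 0.376 and 0.28. Both pairs lie in the direction of the hypothesis, but their difference was not tested for error, and entinostat raised a smaller share of genes at background than of all genes.

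The average effects were set against 100 splits, in which the 8 group labels were dealt freely over the 16 arrays, the real one included. For entinostat the real split gave 3977 genes and the highest of the other splits 2966, and 1 of 100 gave as many as the real one. For doxorubicin the real split gave 7047, the highest other 603, and again 1 of 100 reached it. Where labels were exchanged only between arrays alike in the other drugs, which keeps the effects of those drugs out of the spread, the highest other split called 2393 genes for entinostat and 4328 for doxorubicin, and 1 of 100 reached the real count for each. No other split reached the real count for either drug, which argues against a random assignment of labels for these samples. The free splits put the drug effects into the spread, so the exchange between arrays alike in the other drugs is the closer measure. Since the replicates may be technical, chance differences between cultures were not measured.

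For ATRA the real split gave 19, and 3 of 100 gave as many. The highest other split called 5259 genes, far above the real count. A free split can set arrays with doxorubicin or entinostat mostly on the same side, and the make-up of that split was not examined. Free splits also put the effects of the other drugs into the spread and measure chance poorly for ATRA. With labels exchanged only between arrays alike in the other drugs, 4 of 100 gave as many genes and the highest other split called 175. Of these other splits, 27 called any gene, so chance is not excluded for the ATRA count. DHRS3, named in advance, lay at 8.229 to 9.556 on the 8 arrays with ATRA and at most at 7.462 on the 8 others.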
